A study of Homo sapiens with 2 samples.

How the data were processed

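Messenger RNA levels were measured in MDA-MB-231, an established human triple-negative breast cancer cell line, on 2 arrays: 1 of cells transfected with a microRNA negative control and 1 of cells transfected with a miR-4306 mimic, a synthetic duplex that raises the cellular level of this microRNA. RNA was taken after 48 h. Per the labels' protocols, RNA was prepared with TRIzol and 100 ng of total RNA was turned into biotin-tagged cRNA with a GeneChip IVT kit. The probe table names the array as a human expression GeneChip with many short-oligonucleotide probe sets, each of which sums several probes near the 3′ end of a transcript.

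The deposited table holds, per probe set and array, 1 summarised signal intensity on a linear scale. MAS5 is the only tool named in the submitters' processing notes, which give it no role, so whether it made the intensity values that the authors deposited or only detection calls is open. The table had 54613 probe sets, with signals from 1.37 to 6781 on the control array and from 1.37 to 6869 on the mimic array, and medians of 9.68 and 9.32. On the control array 41.1% of probe sets shared their exact value with another probe set (41.2% on the mimic array), and 8297 probe sets had equal values on both arrays within 1e-06. MAS5 works on each array alone, so equal values across arrays would not be common in its signals. The scale is linear by its range. The background correction, summary method and scaling behind the values are not given in the sources used here. A method that shrinks dim signals would compress the ratios of dim genes. Detection calls and the platform's control probe sets were not used here, so a planned comparison of spike-in controls was not run. The planned comparison of genes with and without a seed match in their 3′ UTR was not run either, because no transcript sequence was used here.

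Probe sets were named through a platform annotation table: 41091 had 1 gene symbol, 1801 had several and were left unnamed, and 11721 had no entry. Symbols were updated through gene IDs to an NCBI RefSeq table of the GRCh38.p14 assembly, used for names and gene class only; 41037 of the single-gene probe sets matched and 54 kept the older symbol. Signals under the 25th percentile of all values (3.74) were set to that floor and log2 was taken with no pseudocount. Probe sets were kept if the mean of their 2 log2 values was at or above the median over all probe sets, a mean signal of 9.52, which left 27307 probe sets and 12820 genes. Each log2 ratio is mimic minus control, centred on the median ratio of kept probe sets, which was 0 before centring. A gene took the value of its brightest kept probe set. A gene was called 2-fold higher or lower at a log2 ratio of at least 1 or at most -1.

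There was 1 array per group, so no test across genes was made, no p-value is given and no ratio has a replicate check. As a figure for noise within these 2 arrays, the log2 ratios of probe sets of the same gene had a pooled SD of 0.28 over 5946 genes. This figure covers probe noise and differences between transcripts of a gene. It does not cover differences between cultures or transfections. The number of arrays limits the precision.

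Gene lists, the rule for naming genes and the alternatives were set before the data were examined. The median of each of 25 lists was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean level. Such a percentile describes these 2 arrays and is not a p-value. Genes of a pathway vary together, so random lists understate the spread of a real pathway between cultures. The named genes are CDC42 and VEGFA (1 gene and 1 list set in advance are not reported here); the 5 genes of largest ratio in each direction among those above the floor on both arrays whose kept probe sets went one way; up to 8 genes in each direction with at least 2 kept probe sets all past 2-fold; and in each list up to 4 members past 2-fold, or the 2 of largest ratio where none passed. Other genes named in the results, such as HMGA2 and NDRG1, fell outside this rule and were not counted among the named genes. Alternatives of scaling were no centring, quantile normalization and a loess fit on mean level (span 0.4). Further ones were no level filter, only probe sets at or above the 75th percentile of level, and a floor at the 10th percentile or no floor. The mean over a gene's probe sets and thresholds of 1.5-fold and 3-fold were also used. So was leaving out probe sets of the _s_at and _x_at classes, which can match several transcripts or cross-match other genes.

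The steps were tested on simulated data, in which 200 genes of the control array were changed by a known amount with noise of SD 0.28 on the log2 scale, in a run on 12790 genes. Of genes raised by 1.5 on the log2 scale 98.0% were called 2-fold higher, and of those lowered by the same amount 92.9% were called lower; for a change of 0.75 the shares were 16.0% and 6.67%. Of unchanged genes 0.048% were called. Of 200 lists of 25 genes drawn from the 12603 unchanged genes, 2.5% lay outside the central 95% of random lists. The simulated noise was independent between probe sets and held no difference between cultures. The share of unchanged genes called is therefore not an error rate for the real arrays. The simulated lists held unrelated genes, so their share outside does not calibrate lists of pathway genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.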

Results

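Transcript levels were compared between MDA-MB-231 breast cancer cells transfected for 48 h with a miR-4306 mimic and cells transfected with a microRNA negative control, to find the mRNAs that differ when this microRNA is added. miR-4306 shares its seed, the short stretch that pairs with target mRNAs, with miR-185. Each group had 1 array, so every ratio below is a single measurement without replicate error. The log2 signals of all 54613 probe sets on the 2 arrays correlated with a Pearson r of 0.992 across probe sets, which are not independent replicates. For 12820 genes a probe set of sufficient signal was available, and 91.6% of them differed by less than 1.5-fold between the arrays.

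CDC42, a small GTPase that organises actin and cell polarity, had the largest decrease of all genes measured. Its brightest probe set (226400_at) read 806 with the negative control and 182 with the mimic, 4.43-fold lower. The other 2 bright probe sets were 5.52-fold (208728_s_at) and 7.23-fold lower (208727_s_at). The 2 dim CDC42 probe sets were left out by the level filter. The 3 bright probe sets spanned log2 ratios of -2.85 to -2.15, against a pooled SD between probe sets of 1 gene of 0.28. VEGFA, the main angiogenic growth factor, differed little. Its brightest probe set read 1064 and 953 (log2 ratio -0.16), 2 others had log2 ratios of -0.08 and -0.05, and 1 dimmer probe set (210513_s_at) was 1.74-fold lower, at -0.80. All 4 VEGFA ratios were below 0, and the 3 smaller ones lay within the SD between probe sets.

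**Figure D1:**
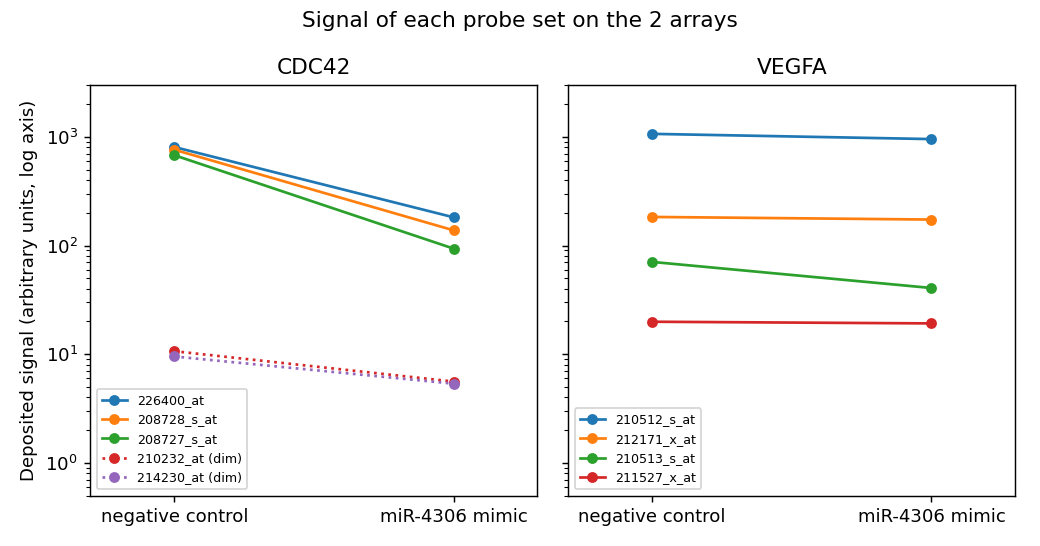
Deposited signal (vertical log axis, arbitrary units) of each probe set of CDC42 and VEGFA on the negative control and the miR-4306 mimic array, 1 array each; dotted lines are dim probe sets left out by the level filter. The 3 bright CDC42 probe sets drop from between 678 and 806 to between 93.7 and 182, while the brightest VEGFA probe set reads 1064 and 953.

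Published targets of the seed family that miR-4306 shares with miR-185 were lower as a group. Of 12 measured members 8 had ratios below 0, with a median log2 ratio of -0.21, below the central 95% of level-matched random lists (-0.12 to 0.23; percentile 0.11). CDC42 was the only member past 2-fold. Under 2-fold, HMGA2, a chromatin architectural protein, had a log2 ratio of -0.81, NFATC3, a calcium-regulated transcription factor, -0.40, DNMT1, the maintenance DNA methyltransferase, -0.31, and RHOA, a regulator of actin contractility, -0.21. HMGA2 probe sets disagreed, from -0.81 to 0.30. SREBF1, a regulator of lipid synthesis, at 0.60, and the kinase AKT1, at 0.45, went the other way. The list holds CDC42 and VEGFA, which were fixed from knowledge of the study, so it is not independent evidence of direction. Without both, 6 of the other 10 had ratios below 0 and 4 above, and none was past 2-fold. Their median was -0.21 (percentile 0.42), but it moved to the 11.9th percentile when probe sets were averaged and to the 14.1th without the _s_at and _x_at probe sets.

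More genes were higher than lower with the mimic. There were 144 genes at least 2-fold higher (1.12% of those measured) and 37 at least 2-fold lower (0.289%). PDK4, which restrains pyruvate oxidation, had the largest increase, from 11.6 to 71.7 (6.20-fold). Among genes whose kept probe sets all went one way it was followed by SPINK4, a secreted protease inhibitor family member (5.54-fold), ANGPT1, a ligand of the TIE2 receptor (4.92-fold), ID3, an inhibitor of basic helix-loop-helix factors (4.57-fold), and KLRC3 (3.67-fold), whose probe set can share signal with near-identical KLRC genes. PDK4, SPINK4, ID3 and KLRC3 each rest on 1 kept probe set. A dim PDK4 probe set left out by the level filter (205960_at) read 4.38 with the control and 4.88 with the mimic. After CDC42 the lowest genes by the same rule were FAT3, an atypical cadherin (log2 ratio -2.01), the cytokine IL11 (-1.84), the nucleoporin NUP58 (-1.79) and the secreted metalloprotease ADAMTS6 (-1.48). The second IL11 probe set had a log2 ratio of -0.63, and the smallest decrease among the NUP58 probe sets was -0.53. ADAMTS6 rests on 1 kept probe set.

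**Figure D2:**
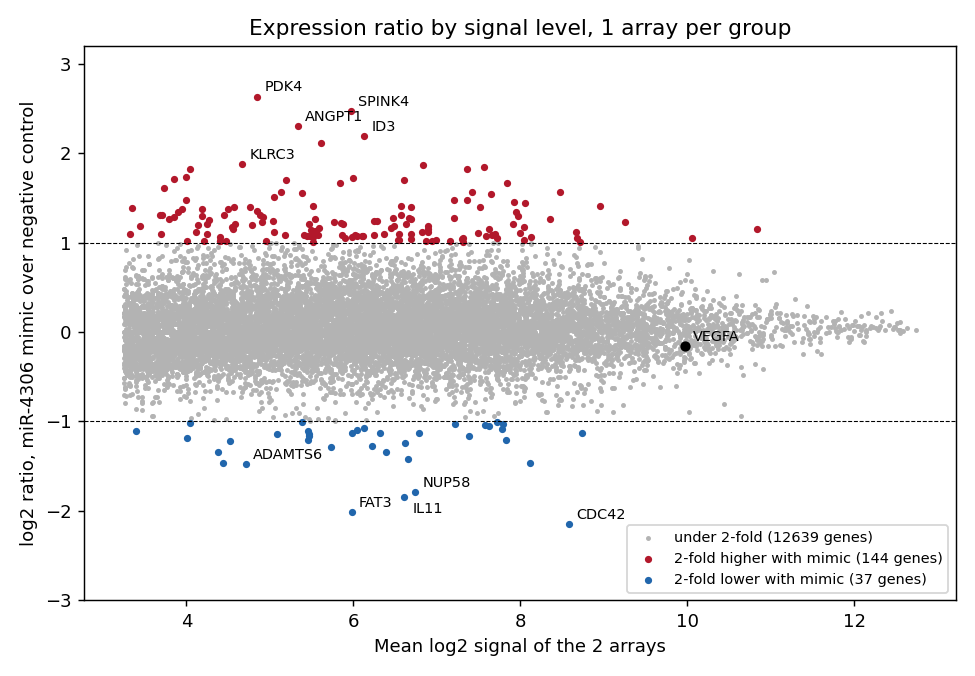
log2 ratio of mimic over negative control (vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis), 1 point per gene, with dashed lines at 2-fold. The 144 higher genes (red) outnumber the 37 lower genes (blue), CDC42 lies lowest, and VEGFA (black) lies close to 0.

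Genes with several probe sets in accord form a shorter list. Of the 70 higher genes with at least 2 kept probe sets, 50 had all of them above 0 and 10 had all past 2-fold; of the 17 lower genes the numbers were 10 and 5. The 5 lower genes were CDC42, FAT3 (log2 ratios -2.01 and -1.70), NBPF20 (-1.21 and -1.13), HBEGF (-1.05 and -1.03) and SCML1 (-1.31 and -1.03). HBEGF is a ligand of the EGF receptor and SCML1 a Polycomb-related protein; NBPF20 belongs to a multigene family whose copies the probes may not separate. Ranked by their smallest probe set ratio, ANGPT1 (2.30 and 2.01) and FAM210B, a mitochondrial membrane protein (1.82 and 1.42), were followed among the higher genes by the endosomal SNARE protein STX12 (1.48 and 1.18). CYP1B1, a cytochrome P450 of oestrogen and xenobiotic metabolism, had 3 probe sets between 1.15 and 1.24 and was bright, at 1222 with the control and 2718 with the mimic. The peptide-processing enzyme CPE was 2.95-fold, the transcription factor TSHZ1 2.60-fold, the histone variant H2AJ 2.09-fold and the γ-secretase subunit APH1B 2.09-fold higher by their brightest probe sets. Both kept H2AJ probe sets are of the _x_at class, which can cross-match other genes.

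Hypoxia and glycolysis genes were higher as a group. Their median log2 ratio was 0.21 over 29 measured members (21 above 0, 8 below), above the central 95% of random lists (-0.08 to 0.15; percentile 99.9). Past 2-fold were ANKRD37, a hypoxia-induced ankyrin protein (1.08), and PFKL, a phosphofructokinase (1.07; other probe set 0.93). Other members were under 2-fold, among them NDRG1 at 0.79, the collagen hydroxylase P4HA1 at 0.77, the glucose transporter SLC2A3 at 0.73 and PDK1, a pyruvate dehydrogenase kinase, at 0.68. Members at or below the list median included PGAM1 at 0.21, ENO1 at 0.08, LDHA at 0.07, GAPDH at -0.0034 and HK2 at -0.43.

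Cell cycle genes showed no 2-fold change. The 32 genes of G2/M and mitosis had a median log2 ratio of -0.08 (19 below 0, 12 above), just under the central 95% of random lists (-0.08 to 0.14; percentile 1.93). KIF23, a kinesin of cytokinesis, was at -0.46 and NUSAP1, a spindle protein, at 0.50 (second probe set 0.07). This placement ended when probe sets were averaged (percentile 3.86) or without the _s_at and _x_at probe sets (8.04). The 34 genes of G1/S and DNA replication had a median of 0.07 (percentile 73.6), with CCND1, cyclin D1, at -0.67 (second probe set -0.72) and E2F1 at 0.59. The seed-family, hypoxia and glycolysis, and G2/M lists were the 3 of 25 outside the central 95%. Lists of unrelated genes would give 1.25 by chance. Genes of a pathway vary together, so the number to expect for these lists is not known.

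Cytokines and angiogenic factors went both ways. In the NF-kB list of 20 measured genes, IL11, the chemokine CCL20 (-1.34) and LIF (-1.08), a cytokine related to IL-6, were at least 2-fold lower and the chemokine CXCL1 was 2.35-fold higher; the other 16 were within 2-fold. The list median of -0.10 lay within the central 95% of random lists (percentile 2.95), but lay below it under quantile normalization (2.45) and without _s_at and _x_at probe sets (0.10), and was 0.03 with no level filter. Among 21 angiogenic factors ANGPT1 and CXCL1 were at least 2-fold higher and HBEGF lower, with a median of 0.16 (percentile 95.3).

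In the matrix protease list the 21 genes were within 2-fold. The plasminogen activators PLAT (-0.94) and PLAU (-0.90, second probe set -1.17) had the largest ratios, and the median was 0.14 (percentile 92.7). Of 19 mesenchymal genes CDH11, a mesenchymal cadherin, was 3.24-fold higher, though its second probe set was at 0.50; the list median was 0.09 (percentile 81.6). The 16 epithelial genes had a median of -0.02 (percentile 25.1) and none past 2-fold, with ELF3 at 0.77 (second probe set 0.21) and CLDN7 at 0.52.

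Stress and innate response genes differed little. Of 30 interferon response genes, which transfected double-stranded RNA can induce, none passed 2-fold; OAS2 and OASL, antiviral enzymes of the oligoadenylate synthetase family, were both at 0.81, and the median was 0.08 (percentile 76.4). In the integrated stress and unfolded protein list of 25 genes, DDIT4, an inhibitor of mTORC1, was 2.40-fold higher, with a list median of 0.09 (percentile 77.9). The 25 apoptosis and p53-responsive genes had a median of -0.04 (percentile 10.96), with the growth arrest genes GADD45A at -0.79 and GADD45B at -0.70.

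Lipid genes followed no common direction. Of 19 cholesterol genes INSIG1, which retains SREBP in the endoplasmic reticulum, was 2.23-fold higher, and the list median was -0.09 (percentile 6.39). The 12 fatty acid synthesis genes had a median of 0.06 (percentile 58.8), with the malic enzyme ME1 at 0.86 and the desaturase SCD at 0.61 (0.22 with its probe sets averaged). Of 12 microRNA machinery genes, TNRC6A was at -0.61 and DICER1 at -0.44, with a list median of -0.14 (percentile 3.02). TNRC6A probe sets disagreed, from -0.79 to 0.18. The 12 DNA methylation genes had a median of -0.02 (percentile 30.8), with TET1 at -0.49 and DNMT3B at -0.46.

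Reference groups were close to 0. The 13 housekeeping genes had a median log2 ratio of 0.04 (percentile 50.1), and the largest were TFRC at 0.32 and PGK1 at 0.26. The 32 ribosomal protein genes had a median of 0.06 (percentile 71.8), with RPL11 at 0.22 and RPL22 at 0.20 (-0.09 with its probe sets averaged and -0.83 without _s_at and _x_at probe sets), and the 32 oxidative phosphorylation genes one of 0.10 (percentile 93.7), with NDUFB5 at 0.25 and NDUFA1 at 0.24. Of 10 histone genes H2BC5 was 3.30-fold higher by a probe set that can match related histone genes, and its other probe set was at 0.36; the list median was 0.06 (percentile 61.6). Markers of other cells showed no 2-fold difference. Over 5 blood genes the median was 0.17 (percentile 82.6), with CD14 at 0.22 and CD3E at 0.20. Over 5 endothelial genes it was -0.11 (percentile 19.6), with KDR at -0.41 and ESAM at -0.21. Over 7 fibroblast genes it was 0.11 (percentile 79.8), with COL1A2 at 0.52 and DCN at -0.50. Over 11 luminal breast genes it was -0.15 (percentile 4.78), with GATA3 at -0.48 and ERBB2 at 0.40.

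**Figure D3:**
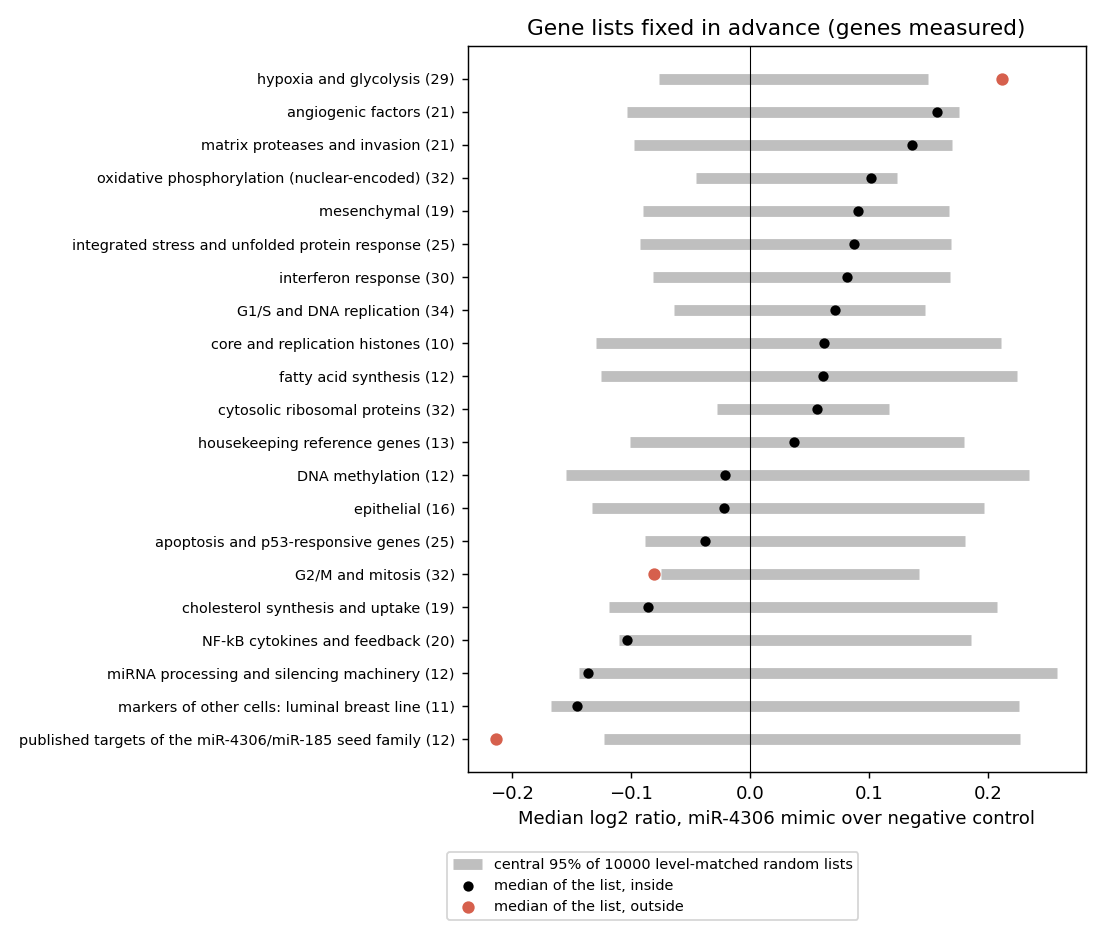
Median log2 ratio (horizontal axis) of 21 gene lists with at least 10 measured genes, the number measured in brackets; grey bars are the central 95% of 10000 level-matched random lists. The seed-family targets (-0.21) and G2/M genes (-0.08) lie left of their bars and the hypoxia and glycolysis genes (0.21) lie right.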

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

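The scaling alternatives were planned before the data were examined; the other tests of this part, and the bounds set for every test, were chosen after the results were seen. Probe sets with no entry in the annotation table were outside the comparisons of genes. Of 3307 such probe sets kept by the level filter, 24 were at least 2-fold higher on the mimic array than on the negative control array (0.726%) and 13 at least 2-fold lower (0.393%). The widest of them were 236180_at, from 11.5 to 55.7, and 237435_at, from 43.4 to 5.84.

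The decrease of CDC42 was weighed first. A single faulty probe set is argued against, since the smallest decrease among its 3 bright probe sets was -2.15 on the log2 scale. The scaling of the arrays is argued against too, since the log2 ratio was -2.19 under quantile and -2.18 under loess scaling. An effect of the mimic on targets of its seed family may account for it: the other 10 published targets had a median at percentile 0.42 of random lists, but at percentile 11.9 with probe sets averaged and 14.1 without _s_at and _x_at probe sets, so this stays open. With 1 transfection per group, a difference between dishes in CDC42 was not tested.

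The excess of higher over lower genes (144 against 37) was weighed next. The scaling, or a trend of the typical log2 ratio with level, is argued against. Under quantile and loess scaling the ratio of higher to lower genes was at least 3.02, against 3.89 in the main setting. It was lower, at 2.04, without _s_at and _x_at probe sets. For probe sets at or above the 75th percentile of level it was 2.59. That setting kept the call of 88 of the 144 higher and 29 of the 37 lower genes, so the excess was smaller among bright probe sets. Neither scaling can remove an excess of increases confined to dim genes, so signal level as part of the cause stays open. Noise of single probe sets was examined only in the 70 higher genes with several kept probe sets. Their 121 other probe sets had a median log2 ratio of 0.60, against an upper limit of 0.04 for random probe sets. This argues against noise as the whole cause of the increases in those 70 genes. It covers neither higher genes with a single kept probe set nor the lower genes, so noise as a cause of the excess stays open. Non-coding transcripts made up 21 of the higher genes (14.6%, against 7.39% of all measured) and none of the 37 lower ones, but among protein-coding genes alone the ratio was 3.32. Indirect effects of the mimic and differences between the dishes stay open and were not tested.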

How the results depend on the processing

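No paired analysis was possible because each group had 1 array, and no replicate could be left out. The seed-site alternatives were not run, since no transcript sequence was used here. No centring, a floor at the 10th percentile and no floor moved no call, because the median ratio was 0 and no called gene lay at the floor; they say nothing about stability. The number of genes at least 2-fold higher (144) was 88 among probe sets at or above the 75th percentile of level and 94 without _s_at and _x_at probe sets, settings that also measured fewer genes (8061 and 9871 against 12820), while the 37 lower genes became 34 and 46. At 1.5-fold there were 765 higher and 306 lower genes, and at 3-fold 18 and 4. Alternatives added after the data were seen gave these counts: genes with at least 2 kept probe sets all past 2-fold numbered 10 higher and 5 lower, and protein-coding genes alone 123 higher and 37 lower. Quantile normalization gave 133 higher and 44 lower, of which 130 and 37 were among the 144 and 37; with probe sets averaged there were 105 and 33, of which 97 and 27 were. No named gene past 2-fold and none of the 3 lists outside the random range changed sign in any alternative run that measured it. Genes dropped by a setting were not scored there, among them PDK4, ANGPT1, KLRC3, ADAMTS6, TSHZ1 and CCL20 at the 75th percentile of level. Averaging cannot change a gene with a single kept probe set, and quantile and loess scaling moved the ratios of named genes little. The kept signs therefore say little about stability. Over the alternatives that changed any value, 11 of 281 values of named genes moved by more than the SD between probe sets and 21 of 146 list medians by more than 1 SD of random lists. The hypoxia and glycolysis list lay between percentiles 98.95 and 99.99 and the seed-family list between 0.10 and 2.35 in every alternative. Without CDC42 and VEGFA the seed-family list lay between percentiles 0.31 and 14.1. Of the reported lists inside the random range, the NF-kB list (0.10) fell below it without _s_at and _x_at probe sets, the NF-kB list also under quantile normalization (2.45), the cholesterol list (1.995) at the 75th percentile of level; the angiogenic (97.9) and interferon (98.4) lists exceeded it at that level and the matrix protease list (98.0) with probe sets averaged. Among the medians that moved, these changed sign or reached 0: NF-kB (-0.10) was 0.03 and mesenchymal (0.09) 0 with no level filter; epithelial (-0.02) was 0.07 and integrated stress (0.09) -0.0043 with probe sets averaged; and without _s_at and _x_at probe sets mesenchymal was -0.15, integrated stress -0.05, housekeeping (0.04) -0.06 and microRNA machinery (-0.14) 0. The cause was not tested. CDC42 was the lowest gene in every alternative run. The number of arrays limits each value: a difference between cultures cannot be told from one due to the mimic.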

Other observations

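Several lists were written after the largest ratios had been seen, so they describe these 2 arrays and are hypotheses only. HIF target genes outside the list fixed in advance were higher: 17 of 19 had ratios above 0, with a median log2 ratio of 0.38 (percentile 99.99 of random lists), including PNRC1 at 0.92, MXI1, a MYC antagonist, at 0.84, BHLHE40 at 0.61 and the collagen hydroxylase PLOD2 at 0.53. FOXO target genes had a median of 0.31 (percentile 99.9), with BMF, a pro-apoptotic BCL2 family member, at 1.41, CCNG2 at 0.79 and TXNIP at 0.76, but without the 4 members already seen the median of 0.22 lay inside the random range (percentile 96.8; just above it, at 98.3 with probe sets averaged and 98.0 without _s_at and _x_at probe sets). SRF/MRTF target genes split almost evenly, 8 of 15 below 0 and 7 above, with a median of -0.19 (percentile 0.19; 4.07 with no level filter; 0.25 without the members already seen, 8 of 13 below 0), with LIMA1 at -0.62 and CNN1 at -0.41, while TPM4 was at 1.34. BMP target genes did not stand apart (median 0.02, percentile 51.2), although ID1 was at 1.31 and ID3 at 2.19.

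ACTR3, a subunit of the actin-nucleating Arp2/3 complex, was picked after its values were seen. Its brightest probe set was at -0.94, short of 2-fold, while its other 3 bright probe sets were at -1.18, -1.29 and -2.44. Probe sets of PPP2R1B, a scaffold subunit of protein phosphatase 2A, disagreed most among genes with bright probe sets at least 0.5 above and below 0: 202883_s_at was at -1.42 and 222351_at at 0.99.

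YAP/TEAD target genes were lower with the mimic: 13 of 21 had ratios below 0, with a median of -0.18 (percentile 0.06), including ANKRD1 at -1.46, AMOTL2 at -0.70, CCN2 at -0.52 and CCN1 at -0.42. That the low median rests only on members already seen is argued against, since the median without them lay at percentile 0.11. Only 10 of those 18 were below 0, however, and none was past 2-fold. For the scaling of the arrays, the highest percentile was 0.07 under quantile and loess scaling. The random lists are matched on level and shift with the scaling, so this percentile could hardly change and decides nothing. Both predictions were written first. The pathway itself was chosen after some of its members had been seen, and genes of a pathway vary together. Random lists cannot measure the bias from that choice, which stays open. A denser or less oxygenated mimic dish could lower YAP targets and raise HIF targets together. The HIF list at percentile 99.99 adds no support, since the hypoxia list was already known to be high. This cannot be told apart from an effect of the mimic or of low CDC42, because each group had 1 dish.

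ERK pathway output genes were also lower, with a median of -0.27 over 25 genes, 17 of them below 0, and -0.13 (percentile 1.09, 10 of 18 below 0) without the members already seen; they included FOSL1, an AP-1 subunit, at -0.89, the receptor EPHA2 at -1.03 and MYC at -0.67. Whether ERK signalling was lower stays open. Its 10 feedback and activity score genes, 7 of them below 0, lay at percentile 0.22, but all 10 belong to the list itself and the test was chosen after most of their values were seen, so it decides nothing; DUSP6 (0.04) and DUSP4 (0.47) were not lower. Other EGFR ligands and AP-1 subunits did not follow HBEGF and FOSL1 (percentile 85.93, but 4.995 without _s_at and _x_at probe sets), which leaves that part open.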
